A study of Mus musculus with 4 samples.

How the data were processed

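RNA from lungs of male C57BL mice was measured on 4 microarrays, 1 for each combination of clean air or mainstream cigarette smoke with 2 or 4 weeks of exposure. Per the series' design text, lung samples of 5 mice were mixed for each array except that of 4 weeks of smoke, which held 4. Per the labels' protocols, total RNA was extracted with the RNeasy Mini Kit, and biotin-labelled cRNA was made with the GeneChip WT PLUS kit. Samples were grouped by their titles. A pool averages its mice, so the spread between animals cannot be seen. With 1 array per group, no group had a replicate pool. The p-values for smoke below set its effect against how much the smoke difference changed between the 2 durations, moderated by a spread estimated across genes. A true change of the smoke effect with duration therefore counts as error, and part of that error may be technical.

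The deposited values are intensities on a linear scale, which the authors summarised and normalised with RMA in Affymetrix Expression Console 1.4.1, per the submitters' processing notes. RMA subtracts background, makes the distributions of the arrays alike and summarises the probes of a feature, so that a shift of all genes in 1 pool would be removed and only differences relative to the other genes remain. The genome build and any filter are not given in the sources used here, and no coordinates are printed. The values ran from 4.93 to 845602, with medians of 58.8 to 61.7 on the 4 arrays. A table on the log2 scale had been foreseen when the tests were chosen, so log2 of the values was taken and the tests were otherwise as planned. Between 541 and 581 features per array lay above 65535, the largest value of a 16-bit scan, and the base with which the linear values were made is not given in the sources used here. If it was e, the log2 differences given would have to be multiplied by 0.69, while directions, ranks and adjusted p-values would be the same. Whether the signal was transformed in any other way is not given either, and such a step could change the folds by other amounts. No background or detection value per feature was used.

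The table held 65956 features. In the array annotation 30604 had 1 gene symbol, 2146 had several and 33206 were not listed; only the first kind was named. Symbols were updated through the Entrez ID with a RefSeq table of assembly GRCm38.p6, which matched 22815 of the 30604 features and changed 827 symbols. Of 30142 genes, 355 had over 1 feature, and the feature with the highest mean over the 4 arrays was used. Genes above the 40th percentile of the mean log2 signal (5.82) were kept, which left 18086, 12585 of them annotated as protein coding. A gene whose Entrez ID was not matched had no biotype and was left out of the protein-coding counts, whether or not it codes for a protein. Among these, 303 shared all 4 values with another gene. The table held 0 columns of other samples.

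For each duration, log2 smoke minus log2 control was taken per gene, and genes at least 1.5-fold different were counted without a p-value. The same was done for the 4-week minus the 2-week control pool as the background, and the difference of the 2 smoke differences was taken per gene. Genes at least 1.5-fold different the same way at both durations were set beside the number that independent lists would share (the product of the 2 counts over the number of genes, per direction). The smoke effect over both durations was tested with limma (lmFit and eBayes) with terms for smoke and duration over all 4 arrays, which leaves 1 residual degree of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all genes above the floor. In this fit a gene passes when its smoke difference is large and alike at both durations. The spread of most genes is then set by the prior that limma estimates across genes, here with 5.38 degrees of freedom.

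The limma step was tested on simulated data for this comparison, with 18086 genes, 200 of them changed, in 20 runs. It recovered 40.1% of genes changed 1.5-fold, 96.6% of those changed 2-fold and 100% of those changed 4-fold or 8-fold. Of its calls, 11.1% were false, which is above the nominal 5%. The simulated noise was independent between genes, with variances drawn from the prior that limma fitted to these data. No duration effect was added, and each changed gene was shifted alike in both smoke pools. The simulation is therefore a favourable case, and real data may give lower recovery and more false calls. The list percentile was tested on 200 simulated lists of 12 genes: 4.5% of unchanged lists lay outside the central 95%, and 100% of lists shifted by 1.5-fold lay above the 97.5th percentile.

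The genes named were taken by a rule: the 12 genes higher and the 12 lower at both durations by at least 1.5-fold with the largest smaller difference; the 6 genes raised and the 6 lowered the most at each duration; the 5 most positive and the 5 most negative differences between durations; the 3 genes raised and the 3 lowered the most between the control pools; and, per gene list, the 4 measured members with the largest mean difference over both durations. Cyp1a1, Cyp1b1, Nqo1, Ahrr, Arntl, Nr1d1, Dbp, Per2, Mmp12, S100a8, Scgb1a1 and Sftpc were always included. Genes outside the rule are marked as named after their values were seen, except in the closing part on other observations. There Krt79, Abcg1, Ccl22, Cry2, Usp2 and the members of 3 further lists are outside the rule too. The 33 gene lists cover xenobiotic, antioxidant and stress responses, the circadian clock, glucocorticoid response, immediate early genes, inflammation, proliferation, lipid synthesis, proteases, matrix and markers of lung, blood and neighbouring cell types. Each list's median was ranked among 10000 random lists of the same size drawn from 20 bins of mean expression. Members of a list can move together, so an extreme percentile is expected more often than in random lists. The groups, comparisons, tests, floor, naming rule, lists and the first set of alternatives were fixed before the data were examined.

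The first set of alternatives was no floor or one at the 60th percentile, the mean of all features of a gene, cyclic loess across the arrays, median centring of each array, a 2-fold limit, an adjusted p of 0.1, no duration term, limma with a trended or a robust prior, and leaving out each array. The natural logarithm in place of log2, genes of equal values counted once, protein-coding genes only, the 2-week control pool as reference for the 4-week smoke pool, limma on the features not named, for the difference between durations the 60th percentile floor, the mean of all features, median centring and the 2-fold limit, and the duration term and the crossed split of the arrays as comparisons were chosen after seeing the data. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.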

Results

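Whole-lung RNA of male C57BL mice, an inbred laboratory strain, was measured after the animals had breathed clean air or mainstream cigarette smoke, the smoke drawn through the burning cigarette. Exposure began at 10 weeks of age and took 1 h per day on 5 days per week, over 2 or 4 weeks, so that the mice were 12 or 14 weeks old at the end. The lungs of a group were mixed before hybridisation. Each of the 4 groups was therefore 1 pool on 1 array, made from 5 mice for the 2-week control, 5 for 2 weeks of smoke, 5 for the 4-week control and 4 for 4 weeks of smoke. The median signal was 61.7 in the 2-week control pool, 60 in the 2-week smoke pool, 58.8 in the 4-week control pool and 61.1 in the 4-week smoke pool. The number of arrays limits the precision of every value. A difference between 2 pools had no replicate check and is given without a p-value, and such genes are described as higher or lower. The words rose and fell are kept for genes whose smoke effect over both durations passed limma at a Benjamini-Hochberg adjusted p of 0.05, with 2 smoke and 2 control pools and duration in the model. An effect written with ± is log2 smoke minus control over both durations with its standard error. All folds assume that the deposited linear values were made with base 2. With base e, each log2 difference would be 0.69 times the value given. Any other transformation of the signal, which the sources used here do not describe, could change the folds by other amounts.

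The first question was which transcripts differed after 2 weeks of smoke. The 6 genes raised the most in the smoke pool, against the control pool of the same age, were Mmp12, the macrophage metalloelastase, at 9.96-fold; Ctsk, the collagen-degrading protease cathepsin K, at 9.01-fold; Gpnmb, a transmembrane glycoprotein of macrophages, at 7.16-fold; Cxcr1, a chemokine receptor, at 7.06-fold; Ccl17, a chemokine that binds CCR4, at 6.88-fold; and Slc26a4, the anion exchanger pendrin, at 6.69-fold. The transcription factor Nr4a1 was 12.7-fold lower, and Fosb and Fos, members of the AP-1 family, were 9.22-fold and 7.01-fold lower. The remaining genes among the 6 lowered the most were Cyp26b1, which degrades retinoic acid, at 6.69-fold lower, Cyp1a1, the cytochrome P450 classically induced through the aryl hydrocarbon receptor (AHR), at 5.07-fold lower, and the immunoglobulin kappa segment Igkv19-93 at 4.88-fold lower. Igkv19-93 was also 5.54-fold lower in the 4-week than in the 2-week control pool. Of 18086 genes above the expression floor, 549 differed at least 1.5-fold, 329 higher and 220 lower, or 285 higher and 269 lower after median centring. Among protein-coding genes the count was 350, with 279 higher and 71 lower. The 2 control pools differed by as much in 740 genes, 267 of them protein coding.

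After 4 weeks, Mmp12 was 25.7-fold, Gpnmb 13.2-fold, Ctsk 12.4-fold, Slc26a4 10.5-fold, Ccl17 9.16-fold and the macrophage scavenger receptor Marco 9.01-fold higher in the smoke pool than in its control. Nr4a1 was 5.09-fold and Fos 4.34-fold lower. The genes S100a9 and S100a8, which encode the abundant neutrophil protein calprotectin, were 4.13-fold and 3.17-fold lower, and Stfa2l1, a stefin gene, was 3.28-fold lower. Nppa, the gene of atrial natriuretic peptide, was 3.08-fold lower. S100a9, S100a8, Stfa2l1 and Nppa were also higher in the 4-week than in the 2-week control pool, by 2.00-fold, 2.91-fold, 2.66-fold and 4.73-fold. In all, 730 genes differed at least 1.5-fold, 458 higher and 272 lower, among them 502 protein-coding genes, 293 higher and 209 lower. Against the 2-week control pool, which differed in age, the 4-week smoke pool differed in 1399 genes.

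The next comparison asked which smoke differences were seen at both durations. Mmp12, Ctsk and Gpnmb again led it. Mmp12 rose by 4.00 ± 0.288 (adjusted p = 0.00309), Ctsk by 3.40 ± 0.135 (adjusted p = 0.000854) and Gpnmb by 3.28 ± 0.201 (adjusted p = 0.00221). Slc26a4 rose by 3.07 ± 0.163, Ccl17 by 2.99 ± 0.130, Vnn1, the pantetheinase vanin 1, by 2.88 ± 0.152 and Cxcr1 by 2.87 ± 0.103. Marco, Retnla (the secreted protein resistin-like alpha), Lcn2 (the iron-siderophore binding lipocalin 2), Clec5a (a myeloid lectin receptor) and Cd68 (a macrophage lysosomal protein) rose by 2.70, 2.39, 2.36, 2.33 and 2.28. Nr4a1 fell by 3.01 ± 0.281 (adjusted p = 0.00749), a mean of 8.05-fold, and Fos by 2.46 ± 0.170 (adjusted p = 0.00285). Ccn1, a matricellular protein, fell by 1.68 ± 0.149, the secretoglobin Scgb1c1 by 1.41 ± 0.128, Apold1, an endothelial early response gene, by 1.35 ± 0.133, the metalloprotease Adamts1 by 1.18 ± 0.101 and Pon1, a paraoxonase, by 1.12 ± 0.101. Cyp26b1 was lower at both durations, but its mean of -1.93 ± 0.337 did not pass (adjusted p = 0.0575).

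In this comparison 266 genes differed at least 1.5-fold the same way at both durations, 205 higher and 61 lower. Lists drawn independently would share 8.33 higher and 3.31 lower genes. The 2 differences shared no array. Opposite differences of that size were seen in 15 genes. Of the 205 higher genes, 145 had the larger difference at 4 weeks, as had 34 of the 61 lower genes. With limma, 265 of 18086 genes passed, 208 rising and 57 falling, and 253 of them were among the 266. All 12 higher genes and 10 of the 12 lower genes picked for their size at both durations passed. The count depended on the scaling, as 72 genes passed after cyclic loess (64 rising and 8 falling) and 8 after median centring (8 rising and 0 falling). It also depended on the genes fitted and on the model: 882 passed when only protein-coding genes were fitted, and 0 without the duration term, where 1163 genes had an unadjusted p under 0.05. Without the 2-week control, the 2-week smoke, the 4-week control or the 4-week smoke pool, 6, 0, 34 and 0 genes passed in fits without duration, with unadjusted p under 0.05 in 1024, 1471, 1448 and 596 genes.

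**Figure D1:**
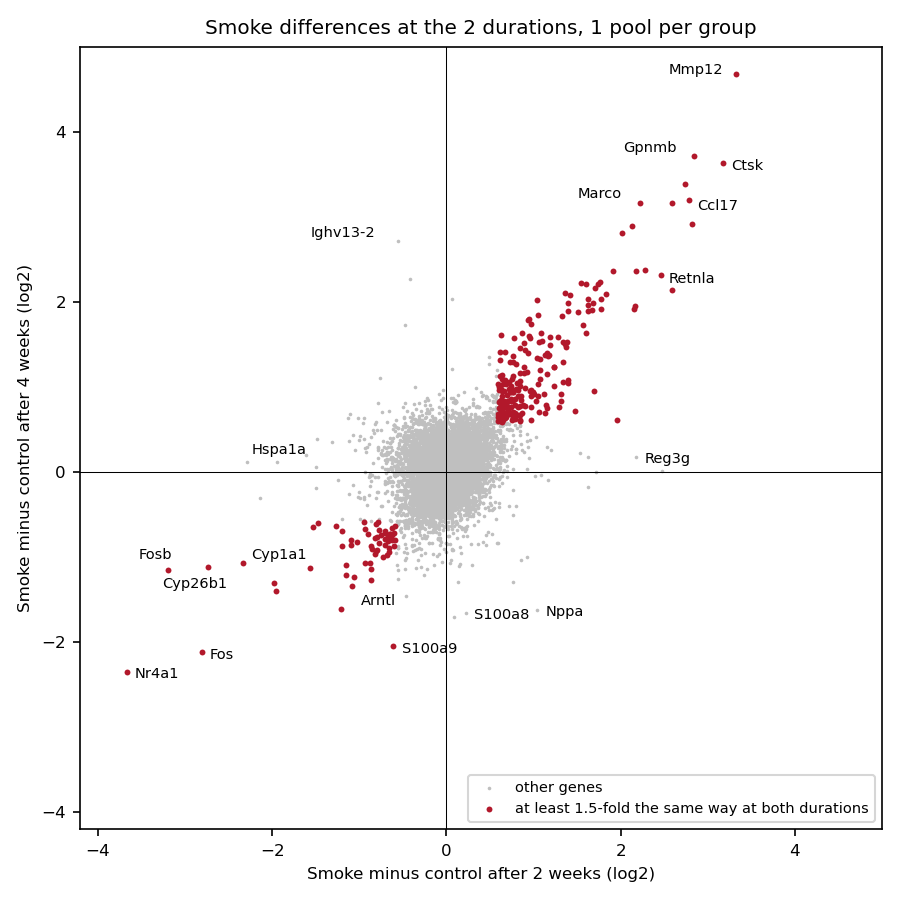
Smoke minus control in log2 units after 2 weeks (horizontal axis) and 4 weeks (vertical axis) for 18086 genes, 1 pool per group. Red points are the 266 genes at least 1.5-fold different the same way at both durations; Mmp12 lies at 3.32 and 4.68, Nr4a1 at -3.67 and -2.35, and S100a8 at 0.22 and -1.66.

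Gene lists fixed in advance were then compared. A list's median smoke difference is given with its percentile among 10000 random lists of the same size and mean expression, which describes these arrays and is not a p-value. Of 33 lists, 13 lay outside the central 95% on the same side at both durations. Lists also lay outside that range between the 2 control pools, so an extreme percentile does not by itself mark smoke. Alveolar macrophage markers stood there at percentile 98.7, and cytokines and monocyte and interstitial macrophage markers at 99.8. Proteases and antiproteases (94.6) and cell cycle genes (12.5) lay inside. Alveolar macrophage markers had the highest medians, 0.92 at 2 weeks and 1.10 at 4 weeks, both at percentile 100. Of 10 measured markers, 6 rose, 1 fell and 3 did not pass; adjusted over the list alone, 7 rose and 2 fell. Marco rose 6.48-fold, Cd68 4.84-fold, Atp6v0d2, a subunit of the lysosomal proton pump, 3.90-fold and the integrin Itgax 3.82-fold. The marker that fell, Fabp1, a fatty acid binding protein named here after its value was seen, did so by 0.87 ± 0.101. After cyclic loess 5 of the 6 rising markers still passed, while the calls of Fabp1 (-0.88) and of the mannose receptor Mrc1, named after its value was seen, were lost. Siglecf, a surface lectin also named after its values were seen, was at -0.13 and 0.13. Monocyte and interstitial macrophage markers had medians of 0.41 and 0.57, both at percentile 100. The complement genes C1qb (1.21 ± 0.112), C1qc (1.06 ± 0.153) and C1qa (0.73 ± 0.101) rose and 7 of 10 markers did not pass; adjusted over the list alone, 6 rose. After cyclic loess, C1qc and C1qa no longer passed.

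Cytokines and chemokines had medians of 0.65 and 1.03, both at percentile 100, and 11 of 20 measured genes rose, none fell and 9 did not pass. Besides Ccl17, these included the chemokines Ccl9 (1.98 ± 0.137), Ccl6 (1.76 ± 0.114) and Ccl3 (1.70 ± 0.153, no longer past the limit after cyclic loess, where 7 of the 11 still passed). Adjusted over the list alone, 16 rose and 1 fell. Proteases and antiproteases had medians of 0.42 and 0.51, both at percentile 100; 5 of 12 rose, and adjusted over the list alone 7 rose and 2 fell. Mmp12 and Ctsk were joined by the lysosomal protease Ctss (1.02 ± 0.150), the gelatinase Mmp2 (0.89 ± 0.104) and the protease inhibitor Timp1 (0.74 ± 0.101), which is named after its value was seen. The calls of Ctss, Mmp2 and Timp1 were lost after cyclic loess. Genes of antigen presentation by MHC class II had medians of 0.84 and 0.57, both at percentile 100. Their median was also 0.36 higher in the 4-week than in the 2-week control pool (percentile 99.8). The class II chains H2-Eb1 (0.84 ± 0.103) and H2-Ab1 (0.81 ± 0.101) and the peptide-loading chain H2-DMb1 (0.72 ± 0.112) rose, while 3 of 6 did not pass, among them the class II transactivator Ciita (0.69 ± 0.116, adjusted p = 0.0514); adjusted over the list alone, 6 rose. Cell cycle genes had medians of 0.45 and 0.65, both at percentile 100. Mki67, a marker of dividing cells, rose by 1.27 ± 0.158, the DNA topoisomerase Top2a by 0.87 ± 0.129, and the spindle genes Kif11 and Tpx2 by 0.79 ± 0.118 and 0.69 ± 0.103; 10 of 14 did not pass, and adjusted over the list alone 10 rose. The 3 MHC class II calls and the 4 cell cycle calls were lost after cyclic loess, with effects of 0.70 to 1.31. Of 13 interferon response genes, 0 passed. Their medians were 0.20 (percentile 99.9) and 0.38 (percentile 100), their median was 0.31 higher in the 4-week than in the 2-week control pool, and 6 rose when adjusted over the list alone.

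Immediate early genes, which are transcribed within minutes of a stimulus, had the lowest medians, -0.93 at 2 weeks and -0.96 at 4 weeks, both at percentile 0.0. Of 13 measured genes, 9 fell and 4 did not pass; adjusted over the list alone, 12 fell. Egr1, a zinc-finger transcription factor, fell by 1.65 ± 0.165. Fosb was at -2.18 ± 0.419 (adjusted p = 0.0811). After cyclic loess only 2 of the 9 still passed, Fos and the antiproliferative gene Btg2, which is named after its value was seen. The other 7 calls were lost, among them those of Nr4a1 (-2.97) and Egr1 (-1.61), as was that of Apold1 (-1.33), which is not in the list. These genes also differed between the control pools. Their median was 0.27 log2 units lower in the 4-week control (-0.27, percentile 0.0), and Nr4a1 was 2.94-fold lower there.

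The circadian clock list moved in both directions. The activator Arntl fell by 1.21 ± 0.113 and the output factor Dbp rose by 1.02 ± 0.108, as did the repressor Bhlhe41 by 1.05 ± 0.114. Per1 fell by 0.70 ± 0.101 and Per3 rose by 0.63 ± 0.101; these period genes are named after their values were seen. The other 12 of 17 clock genes did not pass, among them Npas2 (-0.85 ± 0.155, adjusted p = 0.0688), Nr1d1 (0.49 ± 0.112, adjusted p = 0.134) and Per2 (0.35 ± 0.102, adjusted p = 0.236). Adjusted over the list alone, 8 rose and 5 fell. Between the control pools the list's median was 0.15 higher at 4 weeks (percentile 98.5). For smoke, the medians were 0.16 (percentile 99.8) and 0.08 (percentile 97.8). After cyclic loess, the calls of Bhlhe41, Per1 and Per3 were lost, those of Arntl and Dbp were not, and the 4-week percentile was 96.3. The glucocorticoid and fasting response list had medians of -0.33 and -0.32, both at percentile 0.0. Pdk4, which spares glucose in fasting, fell by 1.00 ± 0.115 and the cell cycle inhibitor Cdkn1a by 0.70 ± 0.109, and 8 of 10 genes did not pass; adjusted over the list alone, 4 fell. Both calls were lost after cyclic loess. This list's median was 0.80 higher in the 4-week than in the 2-week control pool (percentile 100).

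**Figure D2:**
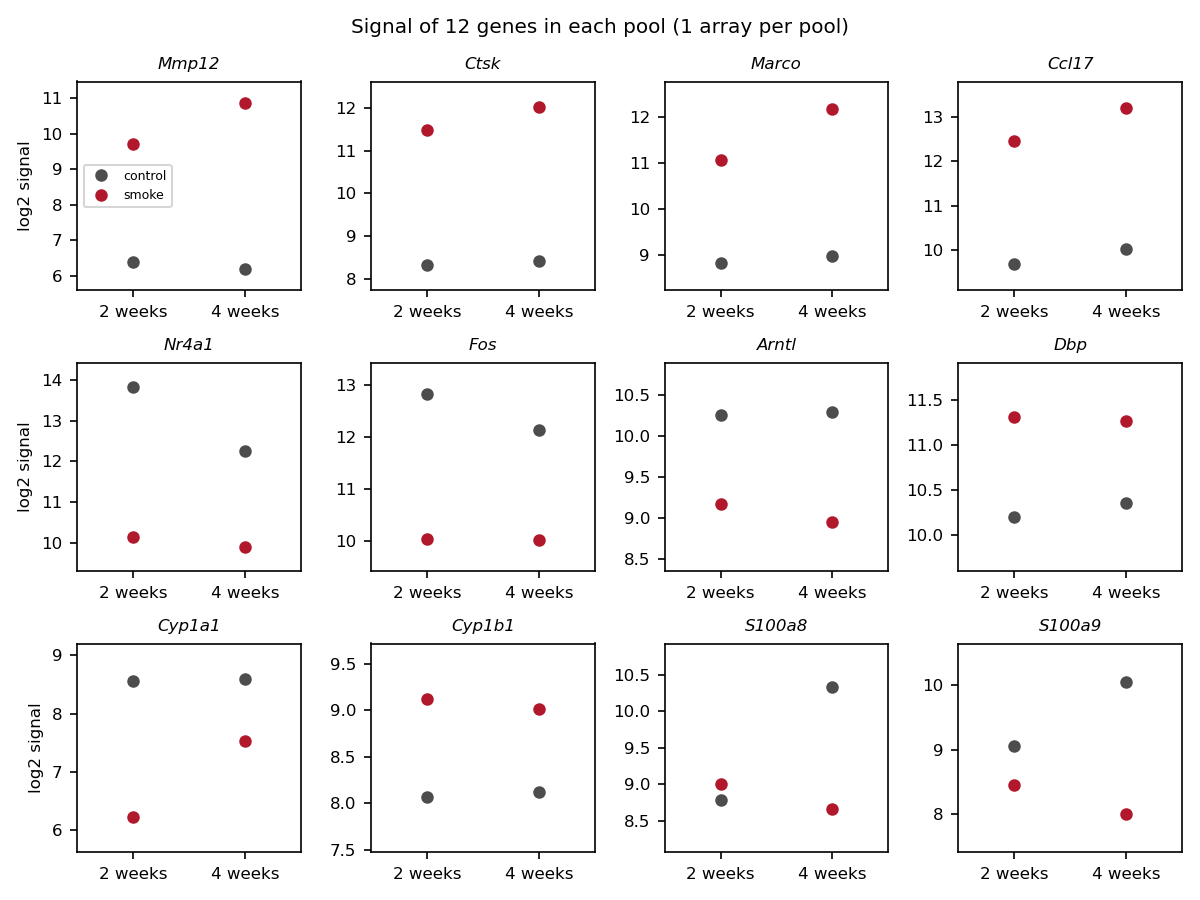
Log2 signal of 12 genes in each pool, with duration on the horizontal axis and 1 array per point (grey, control; red, smoke); the vertical axes differ in range and do not start at 0. Mmp12 lay at 6.40 and 6.19 in the control pools and at 9.71 and 10.87 in the smoke pools, and S100a8 stood at 10.33 in the 4-week control pool against 8.67 to 9.0 in the others.

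Among genes of the response to tobacco chemicals, Cyp1b1, a cytochrome P450 and AHR target, rose 1.95-fold (0.97 ± 0.105, adjusted p = 0.0143), while Cyp1a1 fell 3.27-fold (-1.71 ± 0.271, adjusted p = 0.0434). The Cyp1a1 call was lost after cyclic loess. The other 3 of 5 measured AHR targets did not pass, and the count was the same adjusted over the list alone. The list's medians were -0.21 (percentile 0.8) and -0.13 (percentile 15). Ahrr, the AHR repressor, was at or under the floor in the mean of the 4 pools. Of 25 measured NRF2 antioxidant and glutathione genes, only the cystine transporter Slc7a11 rose, 2.42-fold (1.27 ± 0.113, adjusted p = 0.0068); adjusted over the list alone, 2 rose. The aldo-keto reductase Akr1b8 was at 0.60 ± 0.102 (adjusted p = 0.0541), the heme oxygenase Hmox1 at 0.37 ± 0.105 (adjusted p = 0.226) and the quinone reductase Nqo1 at -0.07 ± 0.115 (adjusted p = 0.909). The NRF2 list's medians were 0.06 (percentile 91.5, or 99.0 after cyclic loess) and 0.07 (percentile 97.2, 97.7 with no floor or 94.0 after cyclic loess). Between the control pools its median was 0.21 higher at 4 weeks (percentile 100). No heat shock chaperone of 10, unfolded protein response gene of 12 or sterol and fatty acid synthesis gene of 12 passed, over all genes or adjusted over the list alone. Heat shock chaperones had medians of -0.37 (percentile 0.0) and 0.12 (percentile 97.3), with Hspa1a at -1.95 and 0.12. Their median was also 0.19 higher in the 4-week than in the 2-week control pool (percentile 98.1). Unfolded protein response genes had medians of -0.13 (percentile 1.5) and 0.14 (percentile 98.6), and sterol and fatty acid synthesis genes of -0.07 (percentile 7.0) and -0.19 (percentile 1.3). Of 10 p53 targets and senescence genes, Cdkn1a fell and 9 did not pass, likewise adjusted over the list alone, with medians of 0.05 (percentile 82.5) and -0.12 (percentile 6.4).

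Few markers of the lung's structural cells passed. Of 11 alveolar type 2 markers, the surfactant protein gene Sftpd rose by 1.03 ± 0.144, a call lost after cyclic loess, and 10 did not pass, likewise adjusted over the list alone. Sftpc, the surfactant protein C gene, was at 0.06 ± 0.102 (adjusted p = 0.918). The list's medians were 0.06 (percentile 85.4) and 0.12 (percentile 90.0). None of 8 alveolar type 1 markers passed; their medians were -0.06 (percentile 23.4) and -0.34 (percentile 0.0), and 2 fell when adjusted over the list alone. None of 11 club and goblet cell markers passed, with medians of 0.27 (percentile 100) and 0.20 (percentile 98.2); 1 rose adjusted over the list alone. The secretory genes Scgb3a1, Reg3g and Bpifa1 were 3.90-fold, 4.53-fold and 3.10-fold higher after 2 weeks of smoke, and also 2.46-fold, 2.94-fold and 3.88-fold higher in the 4-week than in the 2-week control pool. Scgb1a1, the main club cell secretoglobin, was at 0.02 and -0.01. Its log2 signal of 19.63 to 19.69 was the top of the range of each array. RMA makes the distributions of the arrays alike, so a change in this gene could be hidden. Of 12 endothelial markers, Cldn5, a tight junction gene, fell by 0.81 ± 0.102, a call lost after cyclic loess, and 11 did not pass, likewise adjusted over the list alone; the medians were -0.16 (percentile 1.3) and -0.31 (percentile 0.0). Of 12 extracellular matrix and fibroblast markers, the collagen gene Col3a1 rose by 0.71 ± 0.105, a call lost after cyclic loess, and 11 did not pass; adjusted over the list alone, 4 rose. Their medians were 0.16 (percentile 99.5) and 0.05 (percentile 89.9).

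None of the markers of ciliated cells (9 measured), smooth muscle (6), cardiac muscle (10), skeletal muscle (3), adipose tissue (5) or mesothelium and oesophagus (3) passed. Adjusted over the list alone, 4 cardiac and 1 smooth muscle marker fell, with no call in the other lists of this group. Cardiac muscle markers had medians of -0.24 and -0.40, both at percentile 0.0, and smooth muscle markers of -0.07 (percentile 16.9) and -0.58 (percentile 0.0). The cardiac myosin Myh6 was at -0.59 ± 0.101 (adjusted p = 0.0556) and the actin-binding smooth muscle gene Tagln at -0.61 ± 0.140 (adjusted p = 0.133). Ciliated cell markers had medians of 0.22 (percentile 99.5) and -0.03 (percentile 62.7), skeletal muscle markers of -0.16 (percentile 11.0) and 0.04 (percentile 55.0), adipose markers of 0.13 (percentile 92.8) and -0.14 (percentile 4.0, or 2.1 after cyclic loess), and mesothelium and oesophagus markers of 0.24 (percentile 97.0) and -0.39 (percentile 0.4). With no floor, the 4-week median of the mesothelium and oesophagus list was 0.05. Smooth muscle, adipose and mesothelium and oesophagus medians were also higher in the 4-week than in the 2-week control pool. The control differences were 0.38 (percentile 99.9), 0.22 (percentile 98.9) and 0.65 (percentile 100). The 4-week values of these lists can therefore not be set down to smoke alone.

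Among other leukocytes, neutrophil markers had medians of 0.11 at 2 weeks (percentile 93.9) and -0.87 at 4 weeks (percentile 0.0). Beside this stood the control pools, where the median was 0.89 higher at 4 weeks (percentile 100). Of 10 measured markers, the collagenase Mmp8 rose by 1.08 ± 0.138, a call lost after cyclic loess, and 9 did not pass; adjusted over the list alone, 3 rose and 1 fell. T and NK cell markers had medians of 0.15 (percentile 99.0) and 0.11 (percentile 93.4), and 0 of 13 passed, or 2 adjusted over the list alone. Between the control pools their median was 0.17 higher at 4 weeks (percentile 99.3). B and plasma cell markers had medians of 0.15 (percentile 98.6) and -0.18 (percentile 0.5), and 0 of 11 passed, or 1 adjusted over the list alone. With the mean of all probes the 2-week median of the B and plasma cell list was 0.01 (percentile 49.9). The mast cell, basophil and eosinophil list, the erythroid list and the thymocyte list had 1 measured gene each, and none passed over all genes. Cpa3, the mast cell carboxypeptidase, was at 0.48 (percentile 98.1) and -0.41 (percentile 1.8), and with no floor the medians of the mast cell, basophil and eosinophil list were -0.09 and 0.06. Cpa3 was also 0.77 log2 units higher in the 4-week than in the 2-week control pool. Alas2, the erythroid enzyme of heme synthesis, was at -0.46 (percentile 2.6) and -0.61 (percentile 1.8) and fell when adjusted over the list alone. The thymocyte marker Cd8b1 was at 0.06 (percentile 61.5) and -0.12 (percentile 22.5).

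**Figure D3:**
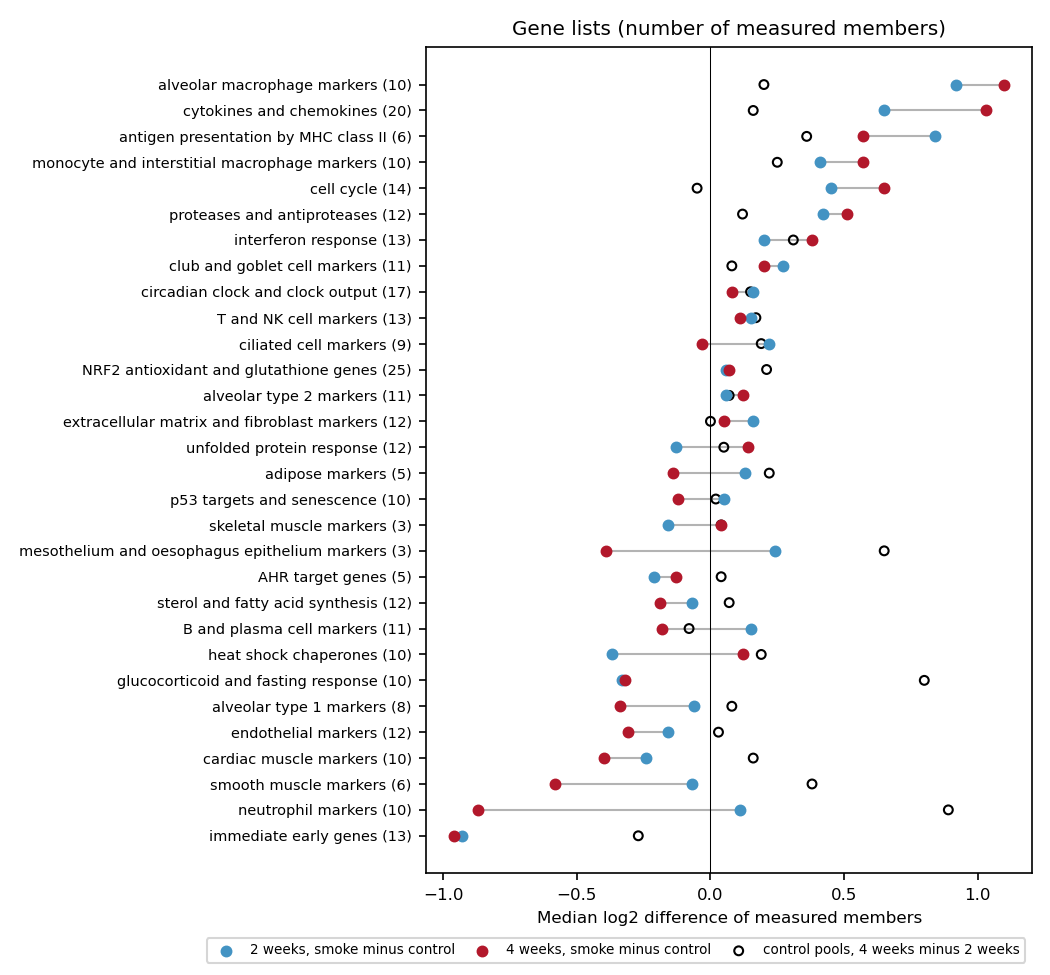
Median log2 difference of the measured members of each list with at least 3 measured members, for smoke minus control at 2 weeks (blue) and 4 weeks (red) and for the 4-week minus the 2-week control pool (open circles). Alveolar macrophage markers and cytokines lay on the right at both durations and immediate early genes on the left; neutrophil markers had medians of 0.11 and -0.87, with 0.89 between the control pools.

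Whether the smoke difference itself changed from 2 to 4 weeks could be given only as a value without a test, since no residual degree of freedom was left. The 5 most positive log2 differences between durations included the immunoglobulin segments Ighv13-2 (3.27) and Igkv19-93 (2.41), the small nucleolar RNA Snora31 (2.22) and the inducible chaperone Hspa1a (2.07). Ighv13-2 was 6.57-fold higher in the 4-week smoke pool than in its control. The most negative were Nppa (-2.66), the predicted genes Gm24463 (-2.47) and Gm22090 (-2.06), the antimicrobial lectin Reg3g (-2.0) and the carbonic anhydrase Car3 (-1.93). In all, 933 genes differed by at least 1.5-fold in this way, 631 more positive and 302 more negative at 4 weeks. This count depended on the floor, with 1794 genes when no floor was set and 488 with one at the 60th percentile. Among protein-coding genes the count was 246, and the balance lay the other way, with 82 more positive and 164 more negative.

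The 2 control pools, which had breathed clean air only and differed in age and duration, gave the background of the same measurement. Gm24463 was 7.79-fold, Nppa 4.73-fold and Tst, a mitochondrial sulfurtransferase gene, 4.24-fold higher in the 4-week control. The predicted genes Gm23442 and Gm26175 were 6.89-fold and 5.80-fold lower, and Snora31 was 5.63-fold lower. At least 1.5-fold differences were seen in 740 genes, 334 higher and 406 lower at 4 weeks. Of these 740, 473 were not annotated as protein coding. They included 68 higher and 319 lower genes with no biotype match, which are not known to be noncoding. Among the 267 protein-coding genes, 248 were higher and 19 lower. The balance also depended on the scaling, with 449 higher and 280 lower after cyclic loess and 262 higher and 508 lower after median centring. With genes of equal values counted once, 334 were higher and 322 lower. In the counterpart of the test at both durations, 44 genes were higher and 107 lower at 4 weeks in both the control and the smoke pools. With limma, 0 genes passed for duration, and 2849 had an unadjusted p under 0.05. For smoke in the same fit 2101 genes had such a p, and 5% of the genes tested is 904.3. The 0 calls therefore do not mean that pools of the 2 durations were alike. Counting genes in which 1 pool stood at least 1.5-fold beyond the other 3, themselves within 1.5-fold of each other, the 2-week control pool stood above in 40 and below in 53, the 4-week smoke pool in 30 and 26, the 4-week control pool in 28 and 17, and the 2-week smoke pool in 1 and 13.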

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

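The differences between durations in this part were not tested, since 1 pool per group leaves no error for them, and the limma tests of unnamed features were chosen after the result was seen. No explanation is offered here. Among the genes named, 5 differed at least 1.5-fold in opposite directions at the 2 durations. The smoke effect at 4 weeks minus that at 2 weeks was -2.66 for Nppa, -2.06 for Gm22090, -1.93 for Car3 and -1.89 for Tst, all higher in the 2-week smoke pool and lower in the 4-week smoke pool than in the control of that duration. It was 1.65 for Gm26175, which was lower at 2 weeks (-1.01) and higher at 4 weeks (0.64). The first 4 were 4.73-fold, 3.0-fold, 2.52-fold and 4.24-fold higher in the 4-week than in the 2-week control pool, and Gm26175 was 5.80-fold lower.

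The medians of 3 gene lists lay outside the central 95% of random lists on opposite sides at the 2 durations. The 4-week minus the 2-week median was 0.27 for unfolded protein response genes, -0.33 for B and plasma cell markers and -0.89 for mast cell, basophil and eosinophil markers. The last of these lists rested on Cpa3 alone, and with no floor its medians were -0.09 and 0.06. For B and plasma cell markers, the 2-week median was 0.01 (percentile 49.9) with the mean of all probes and 0.08 (percentile 90.1) with no floor, so only the unfolded protein response list lay on opposite sides under all 4 settings tried.

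Features that were not named also differed the same way at both durations. Of 14407 features above the floor with no symbol in the annotation, 120 did so by at least 1.5-fold, 48 higher and 72 lower, against 4.8 and 12.9 for independent lists; 963 of these features differed as much between the control pools. With limma and terms for smoke and duration, 80 of the 14407 rose and 118 fell, in a fit whose prior gave every feature the same spread. Of 1343 features with several symbols, 14 did so, 13 higher and 1 lower, against 0.6 and 0.3, and 60 differed as much between the control pools; in limma, 1 of the 1343 rose and 0 fell, with 169 at an unadjusted p under 0.05.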

How the results depend on the processing

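The natural logarithm in place of log2, protein-coding genes only, genes of equal values counted once and the other reference pool were tried only after the data were seen, as were, for the difference between durations, the stricter floor, the mean of all probes, median centring and the 2-fold limit. Of the 149 genes above the floor that the rule named, no called gene changed direction after cyclic loess or with the mean of all probes. No call changed with the mean of all probes, and 23 were lost after cyclic loess, where the effects moved little (Nr4a1 from -3.01 to -2.97) and the prior degrees of freedom fell from 5.38 to 3.64. The 266 genes different at both durations became 114 with the natural logarithm and 80 at 2-fold, and stayed within 1.5 times under the other 7 settings. After 2 weeks, the 549 genes became 210 with the natural logarithm, 350 with protein-coding genes only and 136 at 2-fold. After 4 weeks, the 730 became 268, 158 at 2-fold and 1399 against the 2-week control pool, for which the cause was not tested. Between the control pools, the 740 became 233 with the natural logarithm, 267 with protein-coding genes only and 139 at 2-fold. The difference between durations (933 genes) became 1794 with no floor, 488 at the stricter floor, 287 with the natural logarithm, 246 with protein-coding genes only and 134 at 2-fold. The fall in counts with fewer genes, a smaller log scale or a higher limit follows from those settings. The 265 limma calls became 72 after cyclic loess, 8 after median centring (prior 3.26), 882 with protein-coding genes only (prior 12.23), 0 with no duration term (1163 unadjusted) and 434 at an adjusted p of 0.1. Leaving out 1 array each, without the duration term, gave 0 to 34; fewer arrays and no term for duration were changed together. In the other fits the count ranged from 224 to 379. Genes called in every fit with duration, median centring aside, numbered 58, 51 of them rising, and the 8 of the centred fit were among the 265. With 1 residual degree of freedom most of the weight falls on the prior. Split so that smoke and duration cross, the arrays gave 0 calls (228 unadjusted). With no floor, the list medians reversed for mast cell, basophil and eosinophil markers (-0.09 at 2 weeks and 0.06 at 4 weeks) and for mesothelium and oesophagus markers at 4 weeks (0.05); the cause was not tested beyond the added low genes. The duration term already sets each smoke pool against the control pool of its duration. No further pairing was possible, since each group was 1 pool on 1 array.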

Other observations

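The tests on 3 further gene lists below were written before their members were looked at, the medians of the other lists at each duration after cyclic loess were among the alternatives fixed before the data were seen, and the other tests in this part were chosen after the result was seen. The first 2 hypotheses were that further genes of lipid-laden macrophages and of the osteoclast type were higher in smoke, and both lists' percentiles passed the limit set in advance. Of 11 measured genes known from lipid-laden macrophages, the scavenger receptor Msr1 rose by 1.70 ± 0.124, the lipid receptor Trem2 by 0.86 ± 0.135 and the fatty acid binding protein Fabp5 by 0.77 ± 0.103 in smoke, and 8 did not pass in limma. After cyclic loess the calls of Trem2 and Fabp5 were lost. The lysosomal lipase Lipa (0.69 ± 0.116, adjusted p = 0.0520) and the lectin Lgals3 (0.72 ± 0.127, adjusted p = 0.0607) were close to the limit, while Cd36 was at -0.22 ± 0.101, Lpl at 0.02 ± 0.102 and Apoe at 0.12 ± 0.111. Abca1 was lower at both durations (-0.38 and -0.16), as was Cd36 (-0.24 and -0.19). The medians were 0.24 and 0.59, and the percentile among matched random lists was 100 at both durations. Of 8 measured osteoclast-type genes, a class to which Ctsk, Atp6v0d2 and Mmp12 also belong, the acid phosphatase Acp5 rose by 1.07 ± 0.122, a call lost after cyclic loess, and 7 did not pass. Of the 8, 3 were lower in smoke at 4 weeks, Car2 (-0.24 at 2 weeks and -0.29 at 4 weeks), Itgb3 (0.03 and -0.30) and Nfatc1 (0.19 and -0.13). The medians were 0.28 and 0.13, and the lower of the percentiles at the 2 durations was 98.3. Between the control pools, Clcn7, Itgb3, Tcirg1, Acp5 and Nfatc1 were 0.41, 0.20, 0.19, 0.18 and 0.11 higher at 4 weeks. Car2, Tnfrsf11a and Ostm1 were lower there (-0.30, -0.18 and -0.05). The 4-week smoke median of 0.13 was thus no larger than the clean-air differences of several members. Neither set of percentiles separates more macrophages from macrophages with altered transcription, and the wider osteoclast-type set moved far less than Ctsk or Mmp12.

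Retnla, Ccl17 and Ccl22 are known from alternatively activated macrophages, and a hypothesis was that other genes of that state were higher as well. The limit set in advance, a median above the central 95% of random lists at both durations, was not reached. Of 5 measured genes, 0 passed in limma, with medians of 0.04 (percentile 61.7) at 2 weeks and 0.17 (percentile 94.8) at 4 weeks. All 5 had effects above 0 over both durations, so a smaller rise is not excluded; Mgl2 was at 0.56 ± 0.104 (adjusted p = 0.0718) and Irf4 at 0.26 ± 0.109. Arg1 lay under the floor.

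Alveolar macrophage markers were higher in both smoke pools. The list's median over both durations was 1.04 after cyclic loess, so the shift did not come from a scaling difference that loess removes. Loess was run on values already normalised with RMA and cannot test RMA itself. Both control pools carried the difference, with 6 of 10 markers at least 1.5-fold higher in both smoke pools than in both control pools. That restates the pattern and is no separate test of a single unusual control pool. A larger number of alveolar macrophages of unchanged makeup would raise every marker. Over both durations 3 of 10, Siglecf (-0.0), Krt79 (-0.32) and Fabp1 (-0.87), were under the 1.5-fold limit. The others ran from 0.66 (Abcg1) to 2.70 (Marco), with a median of 1.93. The values of Siglecf, Krt79 and Fabp1 go against a larger number as the whole cause, for these markers only. The markers were split by values already seen, so the gap between the groups is no separate test. Entry of other macrophages (monocyte and interstitial markers had medians of 0.41 and 0.57) and altered transcription within macrophages under smoke also stay open, untested.

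Neutrophil markers were lower after 4 weeks of smoke. After cyclic loess the 4-week median was still -0.82, so the fall did not come from a scaling difference that loess removes. Loess was run on values already normalised with RMA and cannot test RMA itself. A 4-week control pool richer in neutrophil RNA than the other pools may account for it, since 7 of 10 markers were highest in that pool and the 4-week smoke pool differed from the 2-week control pool by a median of -0.12. The 4-week control exceeded the 2-week control by 0.89, while the smoke pools differed by -0.29. An effect of smoke at 4 weeks against a rise with age stays open, as 1 pool stands for each group.

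Immediate early genes were lower and clock genes shifted in both smoke pools. Both control pools carried the difference, with 9 of 13 immediate early genes at least 1.5-fold higher in both control pools than in both smoke pools. That restates the pattern and is no separate test of a single control pool with high immediate early RNA. The median effect of 9 later-peaking clock genes exceeded that of 5 earlier-peaking ones by 0.98; 4 of the 5 earlier genes were lower and all 9 later genes higher. Per1, Cry2 and Usp2, all lower, were in neither group; counted as later genes, they made the gap 0.90, with 3 of 12 lower. Such a shift may come from lungs of smoke and control mice removed at different times of day or after different handling, or from smoke itself moving the clock, which cannot be told apart, because the labels give the hour of exposure but not that of lung removal.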
